A study of Mus musculus with 9 samples.

How the data were processed

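RNA was sequenced from 9 samples of mouse cortex, 3 naive, 3 with EAE and 3 with EAE treated with Au18(L-NIBC)14, as libraries of poly(A) RNA per the labels' protocols. The titles number the brains 1 to 3 in each group, and no label ties a number in one group to the same number in another. The deviations of same-numbered EAE and treated libraries from their group means correlated at 0.17, 0.24 and 0.24, which was not so for all pairs with naive libraries. Per the series' design text, reads were checked with FastQC and trimmed with fastp, aligned with Hisat2 and quantified with bowtie2, and genes were called with DESeq2 at an absolute log2 fold change above 1 and a false discovery rate under 0.05. Per the submitters' processing notes, the FastQC version was 0.11.8 and the genome build mm10, the same assembly as GRCm38. The gene annotation, the strand setting and the counting program's options are not given in the sources used here.

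The authors deposited 1 table of raw counts of 34714 gene symbols, of which 7089 were at 0 in all 9 libraries. Columns were matched to samples by title. A further 9 columns of the table match no sample of the series used here and were not used. A count of 2 was 3.80 to 4.43 times as frequent as a count of 1 in each library, a pattern that counting both mates of read pairs would give, so that a count may stand for less than 1 fragment. Counting error is then larger than the counts imply. The dispersion of the model is estimated between samples and takes it in. The 10 genes with most counts took 2.98% to 3.86% of each library, and TMM factors were between 0.98 and 1.02.

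Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, estimateDisp, glmQLFit with robust set and the package's default fit, glmQLFTest), with all 9 libraries and the group as the only factor, which leaves 6 residual degrees of freedom. The p-values were adjusted by Benjamini and Hochberg over 18644 genes, with a threshold of 0.05. The adjusted p given for a gene is from this test unless DESeq2 is named. Standard errors were computed as the absolute log2 fold change divided by the square root of F. CPM values are scaled with TMM factors. Fold changes are on the log2 scale and subject to edgeR's small prior count.

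Gene lists, 46 in all, were written before the data were examined. They cover inflammation and its cells, the inflammasome, glia, neurons, vessels, regions next to the cortex, red cells, redox and stress responses, cholesterol and the clock. A list of fasting genes was added after the data were seen. The 42 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 42 lists of a comparison. As alternatives, camera was run with the correlation estimated for each list and fry was run, which tests whether a list's genes move on balance one way and does not compare them with other genes. Many lists share members: 19 of the 21 tested inflammasome genes and 7 of the 20 glucocorticoid genes are in other lists too. List medians and counts use the edgeR log2 fold changes. In 2 lists that did not pass in treated against untreated EAE, heat shock (median 0.13, mean -0.05) and myelin (median 0.16, test lower), the measures differ in sign.

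Genes were named by a rule fixed before the data were examined. For each of the first 2 comparisons it takes the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 0, groups that do not overlap and a symbol that is not a placeholder. It adds Pycard, Nlrp3, Casp1, Il1b, Il18 and Gsdmd, up to 4 members of a described list with the smallest p in the list's direction, and up to 10 genes called in both comparisons. Names outside this rule, such as Drd1, Mbp, Lcn2, Gm46731, Msr1, Hbb-b1, Tekt4, Hspb8, Cspg5, Dgcr8, 9330102E08Rik and AY036118, and a few members of small list counts (H2-T23, Kdr, Slc30a10, Dnajc3, Canx, Map1lc3a, Cd74, Hba-a1, Dbp, Arntl and Sult1a1), were chosen after their values were seen. Coordinates are those of RefSeq for GRCm38.p6.

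Without a stated strand setting, reads of overlapping genes cannot be told apart. In GENCODE M21, exons of Plin4 overlap Hdgfl2, those of Rbm3 overlap Rbm3os, those of Hmgcs1 overlap Gm48342, those of Idi1 overlap Gm48574, those of Cebpd overlap Spidr, those of Txnip overlap Gm15441, those of Pycard overlap Gm45205 and those of Il1b overlap Il1bos, each on the opposite strand. On the same strand, Ugt1a6a shares exons with other Ugt1a genes, Lrch4 with Gm20605, Phyhd1 with Gm28035, Ovgp1 with Gm42890 and Lncppara with Mirlet7b. Exons of Fn1, Slc2a1, Ms4a6c, Kcna6 and Alas2 overlap other genes as well, and Fzd10os is not in that annotation. Hba-a2 and Hbb-bs have near-identical copies, as do several MHC genes. The values of all these genes are uncertain to that extent.

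The fit was tested on simulated counts drawn from the real means, library sizes and dispersions with 200 changed genes, on which edgeR tested 18414 genes and DESeq2 18644. In EAE against naive, edgeR found 62% of genes changed 2-fold and 78% of those changed 4-fold, with 8.5% of its calls false, and DESeq2 1.42.0 found 75% and 83% with 21.4% of its calls false. In treated against untreated EAE, edgeR found 66% and 82% with 6.33% false, and DESeq2 83% and 87% with 17.9% false. In treated EAE against naive, where no gene was changed, edgeR called 0 genes and DESeq2 called 10. In data with 1 list shifted, all 3 list tests called that list and 0 others in EAE against naive and in treated against untreated EAE. Those data were simulated without a correlation between genes. In the real data the correlation estimated within lists ran from -0.053 (cerebellum) to 0.96 (striatum). The simulation thus cannot show how often the list tests call unchanged lists of correlated genes.

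Alternatives were DESeq2, size factors of relative log expression, no filter, a filter of 1 CPM in 3 samples, fits of only 2 groups, a block on the replicate number, each library left out, and an absolute log2 fold change above 1. Chosen after seeing the data were a covariate for striatal tissue, edgeR's newer bias-adjusted fit, a block on the replicate number in a fit of only EAE and treated libraries, and leaving out EAE replicate 1, which had high choroid plexus transcripts, together with treated replicate 1, which had the lowest myelin transcripts. Batch, cage and day are not given in the sources used here, so a difference in any of them that follows the groups cannot be told apart from the groups.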

Results

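Bulk RNA sequencing was carried out on cortex from mice (Mus musculus) in 3 groups of 3 samples. The groups were naive mice, mice with experimental autoimmune encephalomyelitis (EAE, an immune-mediated disease of the central nervous system used as a model of multiple sclerosis), and mice with EAE that received Au18(L-NIBC)14. This compound is a gold nanocluster of 18 gold atoms and 14 ligands of N-isobutyryl-L-cysteine. The series title names its target as the oligomerisation of ASC, the inflammasome adaptor encoded by Pycard. The dose, the schedule and the day of collection are not given in the sources used here. Total counts ranged from 26972179 in naive replicate 2 to 45243553 in naive replicate 1, and 18644 genes had enough counts to be tested. Libraries of a group were compared only to see whether any was a copy of another, and none was, with a chi-square per degree of freedom between 17.3 and 58.2. On the first principal component, which held 28.0% of the variance, the 3 EAE libraries had values from 23.3 to 50.3 and the other 6 libraries lay between -35.5 and 0.175. The p-values of single genes below measure only the spread between these samples. Those of camera compare the genes of a list with other genes and depend on the correlation taken between genes. They are thus no measure of the spread between samples alone.

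Tissue composition varied between libraries within every group. Drd1, a receptor gene of striatal neurons, ranged from 8.93 to 68.5 CPM, with its lowest and highest values both in naive libraries. Ttr, the main transcript of the choroid plexus, was at 828 CPM in EAE replicate 1 and between 1.45 and 85.3 CPM in the others. Mbp, a myelin gene, ranged from 1300 CPM in treated replicate 1 to 4490 CPM in treated replicate 3.

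The comparison of EAE with naive cortex asked what the disease changed. Genes induced by glucocorticoid hormones were higher in all 3 EAE libraries and genes of cholesterol synthesis were lower, with 10 of 20 and 11 of 23 members past the threshold. Haemoglobin transcripts were lower too. As lists at a preset correlation, markers of reactive astrocytes, disease-associated microglia, monocytes and complement were higher, more so in EAE replicates 2 and 3 than in replicate 1, though only 3 of 31, 0 of 30, 2 of 19 and 1 of 20 of them passed as single genes. No list call held with an estimated correlation, where the smallest camera adjusted p was 0.109. With fry, which does not compare a list with other genes, 14 of 42 lists passed, the glucocorticoid and cholesterol lists at fry adjusted p = 0.00135. The edgeR test called 184 genes, 137 higher and 47 lower, and in 4479 of all tested genes (24.0%) the 2 groups did not overlap, where chance gives 10%. With an absolute log2 fold change above 1 as well, 81 genes remained, 70 higher and 11 lower.

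The glucocorticoid list held the gene with the smallest adjusted p, Ddit4, an inhibitor of mTORC1 signalling (chromosome 10, 59949675 to 59951770, GRCm38). Ddit4 rose from 26.97 ± 1.33 CPM in naive to 73.1 ± 6.44 CPM in EAE (SD, n = 3 each), a log2 fold change of 1.44 (SE 0.081, edgeR adjusted p = 0.000179). Sgk1, a kinase named for its induction by serum and glucocorticoids (chromosome 10, 21882184 to 21999903), rose from 54.7 ± 4.49 to 191 ± 25.5 CPM (log2 fold change 1.80, SE 0.20, edgeR adjusted p = 0.0114). Nfkbia, which encodes an NF-kB inhibitor, rose by 1.22 and Cebpd, a transcription factor gene, by 2.05 on the log2 scale (edgeR adjusted p = 0.0114 for both). Of the 20 members tested, 10 passed over all genes and 16 when adjusted over the list alone, all of them higher. The list rose with a median log2 fold change of 1.28 (camera adjusted p = 2.03e-19, and adjusted p = 0.109 with an estimated correlation). Mean values of the list were 0.625, 0.784 and 0.962 in the EAE libraries and at most -0.616 in the naive ones.

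Cholesterol synthesis moved the other way. Hmgcs1, the cytosolic HMG-CoA synthase (chromosome 13, 119690351 to 119708260), fell from 310 ± 7.25 to 161 ± 8.37 CPM, a log2 fold change of -0.94 (SE 0.095, edgeR adjusted p = 0.0114). Stard4, a sterol carrier, had a log2 fold change of -0.66, also past the threshold. In all, 11 of 23 members fell over all genes and 19 when adjusted over the list alone, with none past the threshold in the other direction. The median was -0.47 (camera adjusted p = 3.07e-18, and adjusted p = 0.109 with an estimated correlation). Abca1, which exports cholesterol from cells, rose by 1.02 (SE 0.11, edgeR adjusted p = 0.0114).

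**Figure D1:**
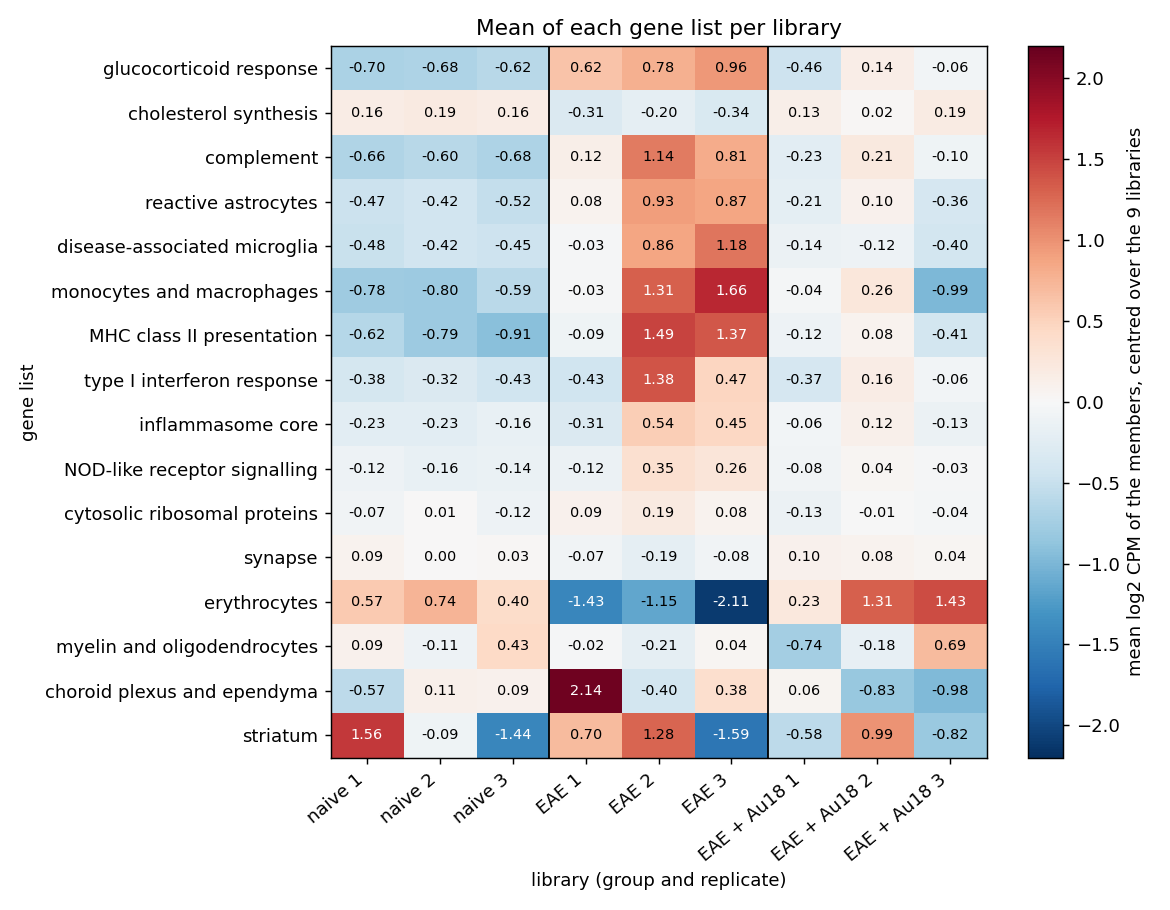
Mean log2 CPM of the members of 16 gene lists (vertical) in each of the 9 libraries (horizontal, by group and replicate), centred over the libraries. The glucocorticoid list lies between 0.625 and 0.962 in the 3 EAE libraries and at or below 0.142 in the other 6, while type I interferon genes are at -0.435 in EAE replicate 1 and 1.38 in EAE replicate 2.

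Among genes that met the naming rule, with a mean log2 CPM of at least 0, the largest rises were in Plin4, a lipid droplet protein gene (log2 fold change 4.53, SE 0.57), Rtp1, which encodes a chaperone of olfactory receptors (chromosome 16, 23429133 to 23433960; 4.23, SE 0.29), and A2m, a protease inhibitor gene (4.03, SE 0.69). Rtp1 went from 0.522 ± 0.126 to 9.78 ± 2.25 CPM (edgeR adjusted p = 0.000611). Ms4a6c, Etnppl, Ugt1a6a, Lrg1, Tmem252, Lrch4 and Hif3a completed the 10 largest of the rule, at 2.12 to 2.95. The largest falls of the rule were in the haemoglobin genes Hbb-bs (-3.36, SE 0.59) and Hba-a2 (-3.31, SE 0.56), followed by Hkdc1 (-1.20), Lsm5 (-1.19) and Fzd10os (-1.18). Lhpp, Idi1 and Mvd fell by 0.86, 0.81 and 0.75 on the log2 scale. Idi1 and Mvd also act in cholesterol synthesis. Some called genes of lower expression moved further, and of these the scavenger receptor gene Msr1 (5.42) had the largest rise and the haemoglobin gene Hbb-b1 (-4.31) the largest fall of all 184 called genes. The erythrocyte list fell with a median of -3.03, Hba-a2 and Hbb-bs of its 8 members past the threshold, and with Hbb-bt, Alas2 and Hba-a1 when adjusted over the list alone (camera adjusted p = 1.54e-05, and adjusted p = 0.207 with an estimated correlation).

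Lists of immune and glial genes rose at the preset correlation, mostly without single genes past the threshold over all genes. Complement had 20 of 20 members above 0 and a median of 1.17. C3ar1, the C3a receptor (2.03, SE 0.30), passed over all genes, and 15 members passed when adjusted over the list alone. Serping1 (1.89) and C3 (4.96) had edgeR adjusted p of 0.0556 and 0.0605. The complement list had camera adjusted p = 2.38e-11, and adjusted p = 0.206 with an estimated correlation. Reactive astrocyte genes had a median of 0.96, with Vim (1.15), Hspb1 (1.35) and Fkbp5 (1.69) past the threshold over all genes and 17 of 31 over the list alone (camera adjusted p = 2.88e-11, and adjusted p = 0.206 with an estimated correlation). Disease-associated microglia genes had a median of 0.70, 0 of 30 members past over all genes and 20 over the list alone (camera adjusted p = 5.95e-11, and adjusted p = 0.213 with an estimated correlation). Monocyte and macrophage genes had a median of 1.53, with Ms4a6c and Fn1 past over all genes and 11 of 19 over the list alone (camera adjusted p = 3.85e-08, and adjusted p = 0.213 with an estimated correlation). MHC class II genes had a median of 1.43, led by H2-Ab1 (3.81) and H2-Eb1 (3.25), with 0 of 12 past over all genes and 7 over the list alone (camera adjusted p = 1.72e-06, and adjusted p = 0.213 with an estimated correlation). NF-kB targets had a median of 0.50, with Nfkbia, Cebpd and Nfkbiz past over all genes and over the list alone these and Socs3 of 24 (camera adjusted p = 1.95e-05, and adjusted p = 0.333 with an estimated correlation). Type I interferon genes had a median of 0.99 and 7 of 34 past over the list alone (camera adjusted p = 2.31e-07, and adjusted p = 0.461 with an estimated correlation). Their list mean in EAE replicate 1 was -0.057 from the naive mean, where the naive SD was 0.057. It was -0.435 in that library against 1.38 and 0.467 in replicates 2 and 3. These 7 lists kept their call whichever library was left out.

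MHC class I genes rose with a median of 0.82, 0 of 19 past over all genes and 5 over the list alone (Tap2, H2-D1, Tapbp, B2m and H2-T23; camera adjusted p = 1.06e-05, and adjusted p = 0.423 with an estimated correlation). Endothelial genes rose (0.26) with Mfsd2a, Slc2a1 and Lrg1 higher over all genes, and 9 higher and 1 lower (Kdr) over the list alone (camera adjusted p = 0.000182, and adjusted p = 0.461 with an estimated correlation). Meningeal fibroblast genes rose (0.92), with Mgp, Nupr1, Bgn and Col3a1 of 22 past over the list alone (camera adjusted p = 0.000346, and adjusted p = 0.474 with an estimated correlation). That rise rests on EAE replicates 1 and 2 (list means 0.581 and 1.07). In EAE replicate 3 the mean was -0.411, below naive replicates 2 and 3 (-0.267 and -0.014). Homeostatic microglia genes rose (0.37) with Sparc and Mertk past over all genes and 7 of 23 over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.474 with an estimated correlation), though not without EAE replicate 2 (0.08, camera adjusted p = 0.179). Cytokines and chemokines rose (0.66), with Cxcl16, Spp1, Cxcl10 and Tgfb1 of 23 past over the list alone (camera adjusted p = 0.00943, and adjusted p = 0.423 with an estimated correlation), though not without EAE replicate 2 (0.51, camera adjusted p = 0.0714). Interferon gamma genes rose (0.57), 0 of 26 over the list alone (camera adjusted p = 0.00992, and adjusted p = 0.605 with an estimated correlation), though not without EAE replicate 2 (0.37, 0.294) or 3 (0.54, 0.173). T cell genes rose (0.53), with Il7r and Il2rb of 15 past over the list alone (camera adjusted p = 0.0277, and adjusted p = 0.213 with an estimated correlation), though not without EAE replicate 2 (0.47, 0.0539) or 3 (0.52, 0.140). Of these lists, 4 were not clearly higher in EAE replicate 1, whose mean differed from the naive mean by -0.00767 for MHC class I (naive SD 0.023), -0.0187 for homeostatic microglia (0.12), 0.0433 for cytokines and chemokines (0.18) and -0.442 for interferon gamma (0.082), so that their rise rests on replicates 2 and 3. Choroid plexus genes rose (1.58) with Trpv4 past over all genes and over the list alone (camera adjusted p = 0.0186, and adjusted p = 0.605 with an estimated correlation). That rise came through EAE replicate 1: without it the median was 0.18, the direction of the test turned and the camera adjusted p was 0.855, and it did not pass without naive replicate 1 either (1.46, 0.107).

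Of lists of cell upkeep, cytosolic ribosomal proteins were higher in 77 of 79 (median 0.19), with Rps14 past over all genes and 11 over the list alone (camera adjusted p = 3.25e-14, and adjusted p = 0.324 with an estimated correlation). Metallothioneins and metal handling rose (0.12), 7 higher and 1 lower (Slc30a10) over the list alone (camera adjusted p = 0.00168, and adjusted p = 0.148 with an estimated correlation). The circadian clock list rose (0.20), with Tef, Cry1, Per2 and Per3 higher and Dbp and Arntl lower over the list alone (camera adjusted p = 0.0257, and adjusted p = 0.461 with an estimated correlation), though not without naive replicate 2 (0.15, 0.149), EAE replicate 1 (0.22, 0.0533) or EAE replicate 3 (0.11, 0.194). Thiol redox genes of the NRF2 response rose (0.13), with Hmox1 and Abcc4 of 29 past over the list alone (camera adjusted p = 0.0286, and adjusted p = 0.423 with an estimated correlation), though not without naive replicate 2 (0.11, 0.081) or EAE replicate 2 (0.10, 0.153). Synapse genes fell (-0.14, lower in 32 of 35, camera adjusted p = 2.76e-05, and adjusted p = 0.213 with an estimated correlation). Cell cycle genes fell (-0.30), with Stmn1, Mcm2 and Mcm5 of 29 past over the list alone (camera adjusted p = 0.000969, and adjusted p = 0.423 with an estimated correlation). Their list mean was -0.321 and -0.438 in EAE replicates 1 and 2. In EAE replicate 3 it was 0.016, above naive replicate 2 (-0.049). Unfolded protein response genes fell (-0.10), with Dnajc3 higher and Hsp90b1, Chac1, Calr, Asns and Canx lower over the list alone (camera adjusted p = 0.00978, and adjusted p = 0.213 with an estimated correlation), though not without naive replicate 1 (-0.04, 0.051).

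The inflammasome was followed gene by gene at the level of RNA, as the stated target pathway. RNA levels do not measure oligomerisation of the ASC protein. Pycard (chromosome 7, 127991373 to 127993867) was at 1.67 ± 0.11 CPM in naive and 3.46 ± 1.27 CPM in EAE, a log2 fold change of 1.05 that did not pass (SE 0.30, edgeR adjusted p = 0.129). Its EAE values were 2.04, 3.85 and 4.48 CPM in replicates 1, 2 and 3. Gsdmd, the pore-forming gasdermin D gene, was at 2.44 ± 0.22 and 5.64 ± 2.28 CPM (1.21, SE 0.29, edgeR adjusted p = 0.0812). Both passed in 3 of 18 alternatives: with DESeq2 (adjusted p = 0.0339 for Pycard and 0.0048 for Gsdmd), without EAE replicate 1 (edgeR adjusted p = 0.0409 and 0.0235) and without EAE replicate 1 and treated replicate 1 together (edgeR adjusted p = 0.0336 and 0.0311). Over all alternatives the adjusted p ran from 0.0336 to 0.312 for Pycard and from 0.0048 to 0.257 for Gsdmd. Nlrp3 (0.22, SE 0.41), Casp1 (0.02, SE 0.59), Il1b (1.04, SE 1.10) and Il18 (-0.01, SE 0.10) did not pass, with edgeR adjusted p of 0.708 or more. Il1b was at or below 0.834 CPM in every library, so that a change would be hard to detect at this depth. For Il18, near 15 CPM, the 95% interval of the log2 fold change ran from -0.24 to 0.22. Txnip, which binds thioredoxin and NLRP3, rose by 1.27 (SE 0.17, edgeR adjusted p = 0.0192) and was the only one of 21 members of the inflammasome list past over all genes. That list rose with a median of 0.36 and Txnip, Gsdmd and Pycard past over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.423 with an estimated correlation). NOD-like receptor signalling had a median of 0.13, with Nfkbia, Txnip and Prkcd higher among 128 members over all genes, and 7 higher and 1 lower (Map1lc3a) when adjusted over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.423 with an estimated correlation). In EAE replicate 1 the list means differed from the naive mean by -0.109 for the inflammasome (naive SD 0.039) and by 0.0153 for NOD-like receptor signalling (naive SD 0.023). Both lists kept their call whichever library was left out.

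**Figure D2:**
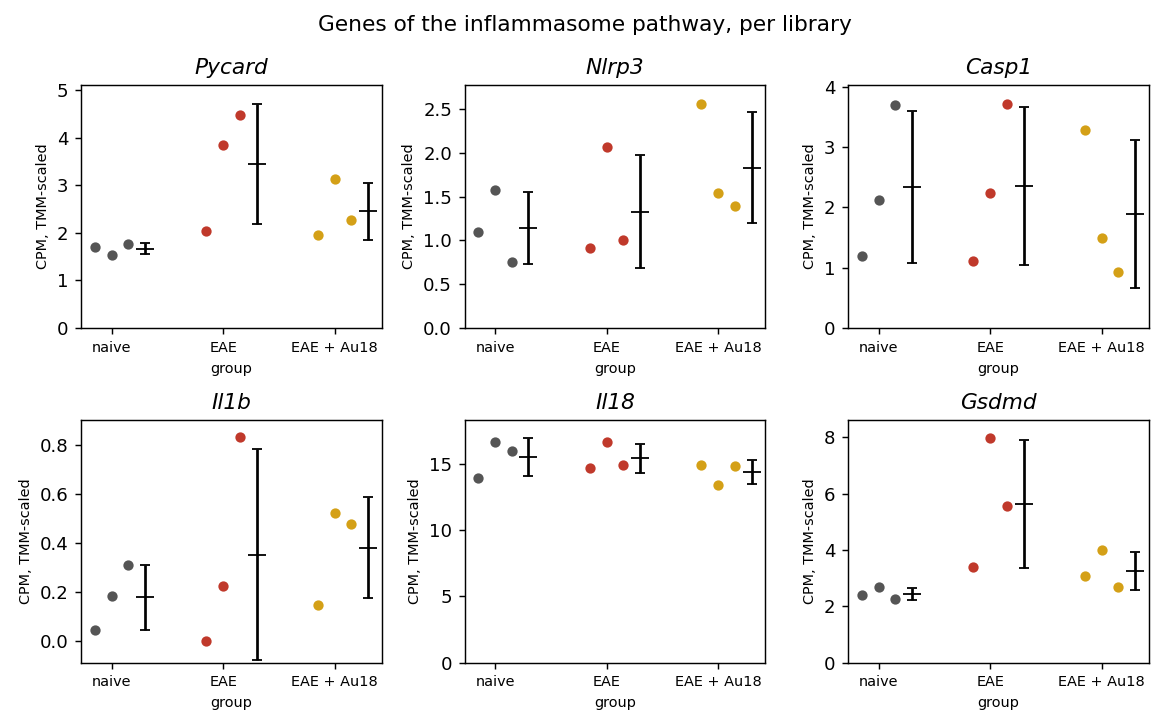
CPM (vertical axis, linear) of 6 inflammasome pathway genes in each library (points) by group, with the group mean and SD (bar, n = 3). Pycard and Gsdmd reach 4.48 and 7.96 CPM in EAE libraries and stay at or below 1.76 and 2.68 CPM in naive ones, while Nlrp3, Casp1, Il1b and Il18 overlap between groups.

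The other 15 lists did not pass in EAE against naive. These were astrocyte identity (median 0.06), myelin (-0.30), oligodendrocyte precursors (0.04), excitatory neurons (-0.14), inhibitory neurons (0.04), immediate early genes (0.02), pericytes (0.21), striatum (0.03), thalamus (0.25), hypothalamus (0.44), hippocampus (0.39), cerebellum (-0.38), olfactory bulb (-0.18), heat shock (-0.14, though its mean was 0.092) and nuclear oxidative phosphorylation genes (-0.02). Of their members, Gjb6, Apod, Prkcd, Hspb1 and Hspb8 rose and Cspg5 fell over all genes. Of the 46 lists, 4 had under 5 members tested and were not used. None of the list calls held with an estimated correlation, where the smallest adjusted p was 0.109. DESeq2 called 1051 genes, among them all 184 of edgeR. The edgeR count fell to 2 without naive replicate 1 (Ddit4 and Rtp1), 7 without naive replicate 2, 19 without naive replicate 3, 34 without EAE replicate 2, 52 without EAE replicate 3 and 87 without treated replicate 2, and was 278 without EAE replicate 1 and treated replicate 1 together. Of the lists, 19 of 27 kept their call in all 9 leave-outs. Each of the 46 genes of the naming rule past the threshold kept its direction in all 9 of these leave-outs of a single library. That follows from the selection, since the groups did not overlap in any of the 184 calls, and is no evidence of stability. Only 2 of the 46 kept their call in all 9.

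The comparison of treated with untreated EAE asked what the nanocluster changed in diseased mice. As lists at a preset correlation, glucocorticoid-induced genes were lower in treated mice and genes of cholesterol synthesis higher, each opposite to its change in EAE. Of their members 4 of 20 and 6 of 23 passed over all genes, and with an estimated correlation neither list did (camera adjusted p = 0.187 for both). With fry, which does not compare a list with other genes, both passed (fry adjusted p = 0.00775 and 0.00609), among 5 of 42 lists. The edgeR test called 41 genes, 17 higher and 24 lower, of which 2 higher and 9 lower also had an absolute log2 fold change above 1. Ddit4 fell from 73.1 ± 6.44 to 30.7 ± 1.13 CPM (-1.25, SE 0.080, edgeR adjusted p = 0.000623) and Rtp1 fell from 9.78 ± 2.25 to 0.875 ± 0.229 CPM (-3.46, SE 0.27, edgeR adjusted p = 0.00214). Shisa4, a membrane protein gene (chromosome 1, 135371057 to 135375298), rose by 0.70 (SE 0.065) and Rbm3, a cold-inducible RNA-binding protein gene (chromosome X, 8138975 to 8145880), fell by 0.73 (SE 0.067), both at edgeR adjusted p = 0.00493. Arrdc2 (-1.66), Sgk1 (-1.42), the collagen gene Col5a3 (-1.41), Lncppara (-1.23), Ovgp1 (-1.15), Sparc (-1.03), Nfkbia (-0.96) and Phyhd1 (-0.96) completed, with Ddit4 and Rtp1, the 10 largest falls of the naming rule. Its largest rise was in Hba-a2 (4.30, SE 0.58, edgeR adjusted p = 0.0456). Lhpp (0.86), Hmgcs1 (0.80), Kcna6, a potassium channel gene (0.65), Sqle (0.61), Stard4 (0.57), Car10 (0.54) and Gramd2 (0.53) also rose. Of called genes of lower expression, Hbb-b1 (5.31) and Tekt4, a tektin gene (-2.24), moved most.

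Of the glucocorticoid list, Ddit4, Nfkbia, Sgk1 and Arrdc2 of 20 members fell over all genes and 15 when adjusted over the list alone, with a median of -0.92 (camera adjusted p = 5.82e-15, and adjusted p = 0.187 with an estimated correlation). Cholesterol synthesis rose with a median of 0.44, with 6 of 23 higher over all genes and 18 over the list alone (camera adjusted p = 1.81e-15, and adjusted p = 0.187 with an estimated correlation). Cytosolic ribosomal proteins fell (median -0.17, lower in 77 of 79, 15 past over the list alone; camera adjusted p = 1.81e-15, and adjusted p = 0.368 with an estimated correlation). Erythrocyte genes rose (3.88), with Hba-a2 past over all genes and the same 5 of 8 as above over the list alone (camera adjusted p = 8.06e-07, and adjusted p = 0.187 with an estimated correlation). Synapse genes rose (0.21, camera adjusted p = 2.53e-07, and adjusted p = 0.221 with an estimated correlation). Unfolded protein response genes rose (0.17), 6 higher and 1 lower (Dnajc3) over the list alone (camera adjusted p = 0.000637, and adjusted p = 0.187 with an estimated correlation). Cell cycle genes rose (0.23), with Mcm2 of 29 past over the list alone (camera adjusted p = 0.000442, and adjusted p = 0.448 with an estimated correlation).

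Several immune and glial lists fell in treated mice at the preset correlation. Homeostatic microglia (-0.14, camera adjusted p = 0.104), astrocyte identity (-0.06, 0.170), T cells (-0.57, 0.0592) and cytokines and chemokines (-0.15, 0.205) did not pass, though Sparc of the first and Gjb6 of the second fell over all genes. In the 6 lists that follow, members passed over the list alone but not over all genes. Reactive astrocyte genes fell (-0.80), 11 of 31 over the list alone (camera adjusted p = 5.83e-09, and adjusted p = 0.263 with an estimated correlation), and disease-associated microglia genes (-0.56), 18 of 30 (1.10e-08 and 0.330). MHC class I genes (-0.73, 9 of 19) and monocyte and macrophage genes (-1.44, with Ms4a6c, Ly6c2, F13a1 and Cd300lf of 19) both had camera adjusted p = 7.20e-06, with 0.532 and 0.394 at an estimated correlation. Complement (-0.69, 6 of 20 over the list alone) had camera adjusted p = 6.68e-05 and MHC class II (-0.87, with H2-Eb1, H2-Ab1, Ctss, H2-Aa and Cd74 of 12) had 0.000379, with 0.394 and 0.412 at an estimated correlation. These 6 lists kept their call whichever library was left out.

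A further 6 falling lists depended on single libraries, and Nfkbia, an NF-kB target, was their only member past the threshold over all genes. Type I interferon genes (-0.67, 0 of 34 over the list alone, camera adjusted p = 8.27e-05, and adjusted p = 0.611 with an estimated correlation) did not pass without EAE replicate 2 (-0.05, 0.533). Choroid plexus genes (-1.69, with Trpv4, Tmem72, Kcne2 and Ttr of 23, camera adjusted p = 8.43e-05, and adjusted p = 0.532 with an estimated correlation) did not pass without EAE replicate 1 (-0.61, 0.103). NF-kB targets (-0.25, with Nfkbia, Cebpd and Nfkbiz of 24, camera adjusted p = 0.00392, and adjusted p = 0.532 with an estimated correlation) did not pass without EAE replicate 3 (-0.10, 0.0769) or treated replicate 1 (-0.17, 0.0781). Interferon gamma genes (-0.66, 0 of 26, camera adjusted p = 0.00392, and adjusted p = 0.618 with an estimated correlation) did not pass without EAE replicate 2 (-0.25, 0.323), EAE replicate 3 (-0.46, 0.145) or treated replicate 1 (-0.47, 0.0912). Meningeal fibroblast genes (-0.47, 0 of 22, camera adjusted p = 0.00557, and adjusted p = 0.618 with an estimated correlation) did not pass without EAE replicate 2 (-0.10, 0.323) or treated replicate 3 (-0.09, 0.395). Hippocampal genes (-0.49, 0 of 21, camera adjusted p = 0.00989, and adjusted p = 0.532 with an estimated correlation) did not pass without EAE replicate 1 (-0.21, 0.167) or treated replicate 3 (-0.36, 0.237).

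In the target pathway, none of 6 genes passed at the level of RNA, which does not test whether the compound acted on ASC oligomerisation. Pycard was at 2.45 ± 0.61 CPM in treated mice (-0.49, SE 0.30, edgeR adjusted p = 0.485) and Gsdmd at 3.26 ± 0.68 CPM (-0.79, SE 0.29, edgeR adjusted p = 0.241). Nlrp3 (0.47, SE 0.40), Casp1 (-0.29, SE 0.59), Il1b (0.11, SE 0.99) and Il18 (-0.10, SE 0.10) had edgeR adjusted p of 0.640 or more. The inflammasome list fell with a median of -0.29 and NOD-like receptor signalling with -0.10 (camera adjusted p = 0.0126 and 0.0389, and adjusted p = 0.564 and 0.584 with an estimated correlation). Nfkbia was the only member of the second list past over all genes, and 0 of 21 inflammasome members passed. Adjusted over the list alone, Txnip of the inflammasome list and Nfkbia, Prkcd and Txnip of the NOD-like receptor list were lower. The inflammasome call was lost without EAE replicate 2 (-0.09, camera adjusted p = 0.260), EAE replicate 3 (-0.22, 0.0886) or treated replicate 1 (-0.28, 0.0512), and the NOD-like receptor call without the same 3 libraries (-0.04, -0.08 and -0.08, camera adjusted p = 0.385, 0.141 and 0.221).

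DESeq2 called 690 genes, among them all 41 of edgeR. The count of 41 fell to 4 without naive replicate 2 or without treated replicate 3 (Ddit4, Rtp1, Shisa4 and Rbm3), 5 without EAE replicate 3 (the same 4 and Car10), 6 without EAE replicate 2, 10 without treated replicate 2, 14 without naive replicate 1 or without naive replicate 3, and 20 without treated replicate 1. It was 14 without EAE replicate 1 and treated replicate 1 together, 64 with the striatal score of each library as a covariate, and 3 in a fit of these 2 groups alone (Ddit4, Rtp1 and Ovgp1). With the replicate number as a block that fit called 4 genes (Ddit4, Rtp1, Gjb6 and Hif3a). With the block in the fit of all 9 libraries Hba-a2, Kcna6, Sqle, Stard4, Gramd2 and Sgk1 did not pass, at edgeR adjusted p from 0.0536 to 0.0734.

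**Figure D3:**
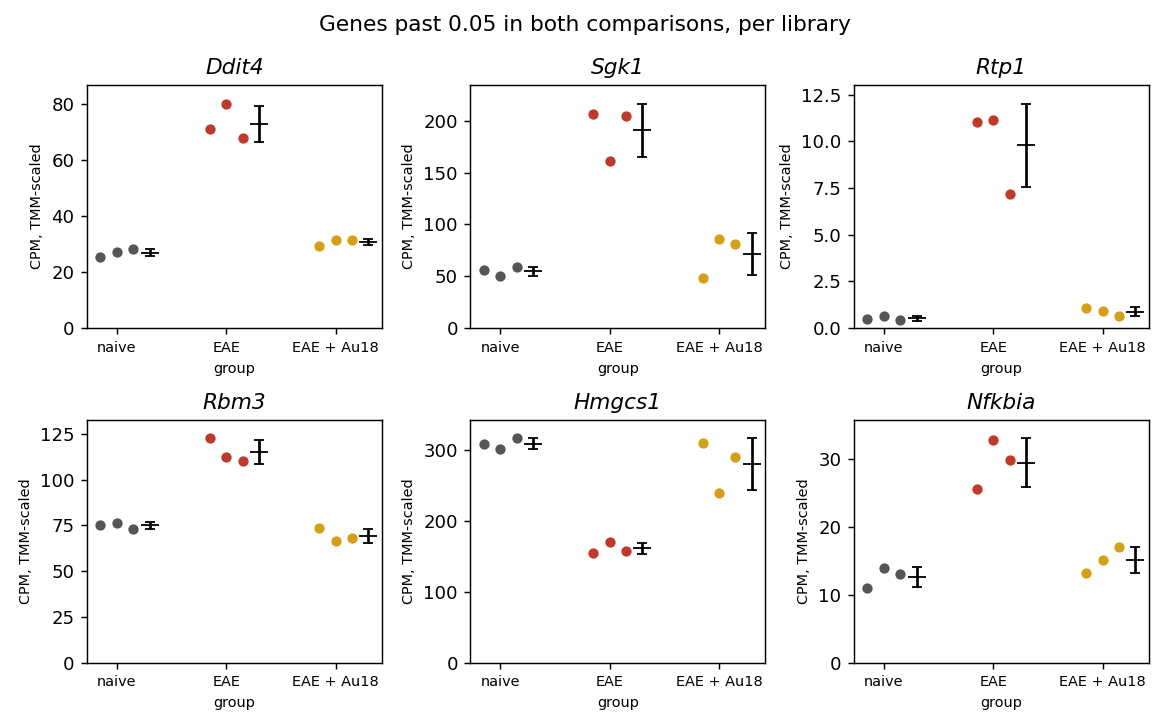
CPM (vertical axis, linear from 0) of 6 genes past the threshold in both comparisons, in each library (points) by group, with the group mean and SD (bar, n = 3). Ddit4 lies at 73.1 ± 6.44 CPM in EAE and at 26.97 ± 1.33 and 30.7 ± 1.13 CPM in naive and treated mice, and Hmgcs1 is lowest in EAE at 161 ± 8.37 CPM.

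The overlap of both lists of changed genes asked which changes of EAE moved back under treatment. Of the 41 genes, 36 were also called in EAE against naive, all in the opposite direction, 21 higher in EAE then lower in treated mice and 15 lower then higher. Ddit4, Rtp1, Shisa4, Rbm3, Lhpp, Abca1, Hmgcs1, Ovgp1 and Phyhd1 were among these 36. Independent lists of these sizes would share 0.18 and 0.043 genes, but both comparisons used the same EAE libraries and are not independent. In 20 simulations of unchanged groups sharing them the overlap was 0, which does not test it, as groups without a change give few calls to share. The 5 genes called only in treated against untreated EAE were Lncppara, 9330102E08Rik, AY036118, Dgcr8 and Kcna6, whose edgeR adjusted p in EAE against naive was between 0.053 and 0.071, and a difference between their changes was not tested. Across all 18644 genes, which are not independent replicates, the log2 fold changes correlated at -0.81 against a simulated mean of -0.50. The covariance was -0.158 against a simulated mean of -0.0482, a difference of -0.11. The simulation drew genes independently and so leaves out the correlation between genes. With 3 EAE libraries no split leaves 2 on each side, so part of the overlap of calls and of the correlation can come from the shared libraries. Of the 42 lists, 20 were called in both comparisons at the preset correlation, all in opposite directions, but none held with an estimated correlation, where the smallest camera adjusted p was 0.109 and 0.187. How often unchanged groups that share libraries give opposite list calls was not simulated. DESeq2 called 500 genes in opposite directions. The overlap was 2 without naive replicate 1 or without naive replicate 2 (Ddit4 and Rtp1), 11 without naive replicate 3, 6 without EAE replicate 2, 5 without EAE replicate 3 (Ddit4, Rtp1, Shisa4, Rbm3 and Car10), 19, 10 and 4 without treated replicates 1, 2 and 3 (the 4 being those 5 without Car10), 3 in fits of only 2 groups (Ddit4, Rtp1 and Ovgp1) and 14 without EAE replicate 1 and treated replicate 1 together.

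**Figure D4:**
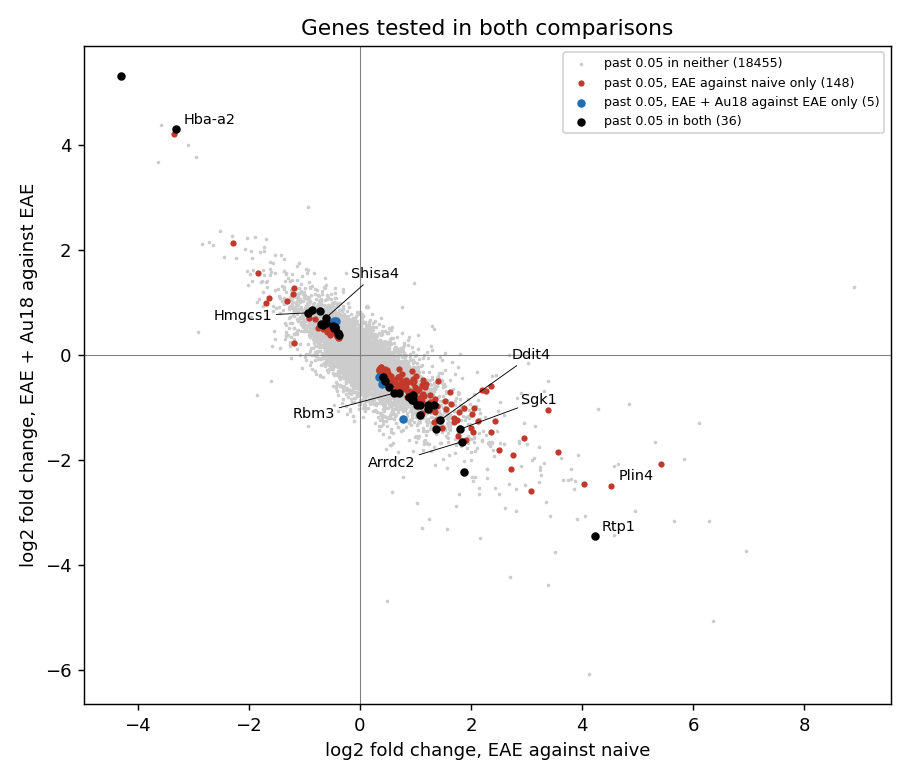
Log2 fold change of each of 18644 genes in EAE against naive (horizontal) and in treated against untreated EAE (vertical), coloured by which test it passed. The 36 genes past the threshold in both changed in opposite directions, and the axes share the EAE libraries, which alone gives a negative slope.

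The comparison of treated EAE with naive mice asked how far treated mice remained from naive ones. No gene passed with edgeR, with 318 genes at an unadjusted p under 0.05 where chance gives 932. In 1165 genes (6.25%) the groups did not overlap, where chance gives 10%. Both numbers lie below chance, so the test may be conservative in this comparison. The absence of calls does not show that treated mice had returned to naive levels. DESeq2 called 3 genes, all higher in treated mice. They were Lrch4 (log2 fold change 1.53), the acute-phase gene Lcn2 (4.90) and Gm46731, which was at 0 in 3 naive, 2 EAE and 1 treated library. Lcn2 was at 0.268 CPM or less in naive and at 2.15, 9.39 and 4.23 CPM in treated replicates 1, 2 and 3. The 137 genes higher in EAE had a median log2 fold change of 1.01 against naive, and 0.24 in treated mice against naive. For the 47 lower genes the medians were -0.61 and -0.04. These genes were chosen on the same EAE and naive libraries, so their change in EAE may be overstated. Part of the drop can come from that choice.

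At the preset correlation, 16 lists passed, 13 higher and 3 lower in treated than in naive mice. Complement (median 0.52, above 0 in 19 of 20 genes) and glucocorticoid response (0.26, above 0 in 16 of 20) had camera adjusted p = 1.15e-08, and adjusted p = 0.514 with an estimated correlation. These 2 kept their call whichever library was left out, with 0 complement and 5 glucocorticoid members (Cebpd, Lcn2, Plin4, Sult1a1 and Hif3a) past over the list alone. The other 11 higher lists were endothelium (0.22), MHC class II (0.47), monocytes and macrophages (0.49), type I interferon (0.29), reactive astrocytes (0.27), NF-kB targets (0.12, with Cebpd past over the list alone), homeostatic (0.16) and disease-associated microglia (0.14), cytokines and chemokines (0.19), NOD-like receptor signalling (0.03) and metallothioneins (0.10). The 3 lower lists were cholesterol synthesis (-0.06), choroid plexus (-0.26) and myelin (-0.09). Apart from the 5 glucocorticoid genes and 1 NF-kB target, 0 members of the 16 lists passed over the list alone. With an estimated correlation each of these 14 had adjusted p = 0.867, except metallothioneins with 0.514. The inflammasome list did not pass (0.14, camera adjusted p = 0.152).

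Each of these 14 lists lost its call without at least 1 library, and the count of 16 fell to 10 without treated replicate 2 and to 9 without treated replicate 3. Without naive replicate 1 the camera adjusted p was 0.0539 for NOD-like receptor signalling, 0.0635 for type I interferon, 0.152 for disease-associated microglia, 0.0764 for reactive astrocytes and 0.138 for metallothioneins. Without naive replicate 2 it was 0.262 for NOD-like receptor signalling, 0.0766 for disease-associated microglia and 0.234 for choroid plexus. Without naive replicate 3 it was 0.0615 for NOD-like receptor signalling and for MHC class II, 0.120 for cytokines, 0.107 for homeostatic microglia, 0.0653 for disease-associated microglia and for reactive astrocytes, 0.514 for myelin and 0.121 for choroid plexus. Without EAE replicate 3 it was 0.051 for NOD-like receptor signalling. Without treated replicate 1 it was 0.0511 for disease-associated microglia, 0.0514 for reactive astrocytes and for monocytes and macrophages, and 0.0963 for myelin. Without treated replicate 2 it was 0.173 for NOD-like receptor signalling, type I interferon and reactive astrocytes, 0.107 for disease-associated microglia, 0.288 for monocytes and macrophages, 0.0912 for myelin, 0.344 for choroid plexus and 0.367 for cholesterol synthesis. Without treated replicate 3 it was 0.230 for NOD-like receptor signalling and choroid plexus, 0.168 for type I interferon, homeostatic and disease-associated microglia, endothelium and metallothioneins, 0.0645 for cytokines and 0.139 for NF-kB targets. The myelin median turned to 0.14 without treated replicate 1, the library with the lowest Mbp, and to 0.033 without naive replicate 3.

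Pycard (0.56, SE 0.30) and Gsdmd (0.42, SE 0.29) did not pass, with 95% intervals from -0.12 to 1.24 and from -0.23 to 1.08.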

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

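The striatal covariate, the bias-adjusted fit, the block in a fit of 2 groups and the removal of both doubted libraries were chosen after seeing the data. Each of the 46 and 24 called genes named in EAE against naive and in treated against untreated EAE kept its direction in every leave-out. The selection fixed this beforehand, since the groups did not overlap in any of the 184 and 41 calls. Of the 46 and 24 genes, 2 and 4 kept their call in all 9. Counts under relative log expression size factors, no filter and the 1 CPM filter were within 1.5 times of those reported. With single libraries left out, 2 to 261 genes were called in EAE against naive, 4 to 38 in treated against untreated EAE and 0 in treated EAE against naive, 2 to 37 genes changed in opposite directions, and 24 to 30, 18 to 28 and 9 to 17 lists were called. Fewer samples cost power, but their number alone does not account for the range in EAE against naive. A fit of only those 2 groups, on fewer libraries, called 174 genes. With 1 library left out the count was 2 without naive replicate 1, 252 without EAE replicate 1 and 261 without treated replicate 3. The counts thus depended on which library was left out, and the cause was not tested.

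DESeq2 called 1051, 690 and 3 genes in the 3 comparisons and 500 in opposite directions, and with an absolute log2 fold change above 1 it called 330, 165 and 3, against 81 and 11 with edgeR. In the simulation 21.4% of its calls in EAE against naive were false against 8.5% for edgeR. Fits of only 2 groups, with fewer samples, called 3 genes in treated against untreated EAE and 3 in opposite directions. The striatal covariate gave 64 genes in treated against untreated EAE. Without both doubted libraries the counts were 278 and 14 genes and 14 in opposite directions. Camera with an estimated correlation called 0 lists in each of the 3 comparisons, and fry called 14, 5 and 0. The 5 were cholesterol synthesis (fry adjusted p = 0.00609), glucocorticoid response and erythrocytes (0.00775 for both), unfolded protein response (0.00923) and synapse (0.0244). Reactive astrocytes (0.0581) and disease-associated microglia (0.0871) did not pass with fry in that comparison. The cause of these moves was not tested.

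Over all 3 groups, 6 of 9 same-numbered pairs had correlated deviations above 0.1, from -0.25 to 0.36, and 6 correlated best with their own number. The 3 pairs of EAE and treated libraries were all above 0.1 and best with their own number, a hint from the data and not the design, while those of naive and treated libraries were at -0.25, -0.12 and 0.20. In a fit of only EAE and treated libraries, the block gave 4 genes against 3 without it, and 24 lists. With the replicate number as a block, 238, 46 and 0 genes were called and 43 in opposite directions.

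Values that turned sign all belong to genes that did not pass or to 2 lists. With single libraries left out, the log2 fold change in EAE against naive ran from -0.47 to 0.52 for Casp1 (highest without naive replicate 3), from -0.25 to 0.51 for Nlrp3 (highest without naive replicate 2), from -0.080 to 0.043 for Il18 and from -0.55 to 1.73 for Il1b. In treated against untreated EAE it ran from -0.95 to 0.19 for Casp1 and from -0.48 to 1.69 for Il1b. Without both doubted libraries Il18 was at 0.031 in EAE against naive, and Nlrp3 and Il1b at -0.080 and -0.079 in treated against untreated EAE. The median of choroid plexus in EAE against naive ran from 0.18, where its test turned, to 1.93, and that of myelin in treated EAE against naive from -0.64 to 0.14, with 0.14 without both doubted libraries. The cause was not tested.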

Other observations

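Tests of the uneven immune lists and of haemoglobin were chosen after those results were seen. The cross-check of the reversal, the simulated covariance, the splits of samples and the fatty acid test were set before their results were seen.

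Genes linked to fasting and lipid use were among the genes called in EAE cortex. Angptl4, a secreted inhibitor of lipoprotein lipase, was higher by 2.03 on the log2 scale (SE 0.35, edgeR adjusted p = 0.033) and Ucp2, a mitochondrial carrier gene, by 1.55 (SE 0.18, edgeR adjusted p = 0.011). Angptl4 and Pdk4 are also members of the glucocorticoid list. Pdk4 (0.31) and Cpt1a (0.16) did not pass. The hypothesis that EAE cortex held a fasting-like response was tested on the other 16 tested genes of a list of fasting and PPAR-alpha targets. Their median was 0.047 with 10 of 16 above 0 and 0 past the threshold, and the camera p was 0.775 with an estimated correlation and 0.566 with the preset one. The median is under the bound of 0.1 set before the test, so the prediction of the hypothesis was not met. The SD of the 16 values was 0.183, which is a spread between genes and not the error of their median. That error was not measured, so a weak response stays open. Angptl4, Ucp2, Pdk4 and Cpt1a were chosen after their values were seen.

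Cirbp, another cold-inducible RNA-binding gene beside Rbm3, was at 86.0, 84.9 and 73.0 CPM in EAE and from 66.8 to 76.1 CPM in naive libraries, overlapping where Rbm3 did not. Rbm3 was at 110 CPM or more in EAE and at 76.5 CPM or less in naive libraries. Xist was between 699 and 993 CPM in every library. Cirbp and Xist were chosen after their values were seen.

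The first pattern is that genes changed in EAE moved back in treated mice. Comparisons that share the EAE libraries give such a mirror by chance. Against this as the whole source, genes chosen on 2 EAE and 2 naive libraries, 221 to 478 at a time, were measured in the EAE and naive libraries left out. Treated libraries had lost a median share of 0.792 of the EAE change, with 0.612 to 0.994 over 9 combinations that are not independent. The covariance of the fold changes was -0.158, below the 20 simulated values from -0.0527 to -0.0457. Simulated genes were drawn independently, so that range may be too narrow for correlated genes and does not decide the question. A biological effect of the treatment stays open as a hypothesis, together with any batch, day or disease score that follows the groups, which was not tested.

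The second pattern is that immune lists were lower in EAE replicate 1 than in EAE replicates 2 and 3, with differences of -1.36 for type I interferon and -1.52 for MHC class II, while that of its glucocorticoid list was -0.25. Against a naive library under an EAE label, its glucocorticoid mean was 1.24 above the highest naive library, where the naive SD was 0.044. Dilution by tissue other than cortex stays open: its excitatory neuron list was higher than in replicates 2 and 3 by 0.107, within the SD of 0.123 of the EAE libraries, and its choroid plexus, hippocampus, striatum and thalamus lists were higher by 2.15, 0.54, 0.85 and 0.24. The glucocorticoid list did not rise through immune genes, since its 13 members that no other list holds had a median of 1.35 and were all higher in EAE against naive. A mouse at another stage or severity may account for it as well, and no label gives either, so that no biological explanation was tested.

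The third pattern is lower haemoglobin in EAE. The 6 globin genes summed to 151 ± 22.1 CPM in naive, 15.6 ± 8.25 in EAE and 274 ± 150 in treated mice (SD, n = 3). Against reads shared between globin copies, the sum itself fell, with a log2 ratio of -3.28. The endothelium list had a median of 0.26 (camera adjusted p = 0.461 with an estimated correlation). Endothelial transcripts thus did not fall as a list, with 20 of 28 members higher and 8 lower. The list mean was -0.03 or more in the EAE libraries and -0.193 or less in the naive ones. These values argue against fewer blood vessels as the source of a fall of this size, though transcripts do not count vessels. Less red cell RNA in the tissue may account for the lower haemoglobin. Alas2, which makes haem in red cells and is no globin, had a log2 fold change of -3.10 (SE 0.63, edgeR adjusted p = 0.060). Bpgm (0.017) and Fech (0.037), which other cells express too, did not fall. Whether less blood stayed in the tissue at collection or the blood held fewer young red cells was not tested.

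Other divisions of the 6 samples of a comparison into 3 and 3, with the third group kept, number 10 with the real one, too few for a share under 0.05. In EAE against naive 1 of 10 reached the real count of 184, and the highest other was 0. In treated against untreated EAE 1 of 10 reached 41, and the highest other was 0, splits that part all same-numbered pairs included. In treated EAE against naive the real count was 0, which 10 of 10 reach by construction, so that the splits test nothing there, and the highest other was 2.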
